A study of Rattus norvegicus with 6 samples.

How the data were processed

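RNA sequencing of rat brain was analysed in 6 libraries, 3 with the empty plasmid pcDNA3.1 (vector) and 3 with pcDNA3.1 carrying LINC00894, grouped by the genotype label. Replicates were numbered in accession order, and these numbers pair nothing. Per the labels' protocols, RNA was extracted with TRIzol, selected for poly(A), primed at random and sequenced as paired ends. The submitters' processing notes name HISAT2 2.0.1 and DESeq2 without giving their roles. The counting tool, annotation release and genome build are not given in the sources used here, nor whether counting used strand, so overlapping and antisense genes cannot be told apart.

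The authors deposited 1 table of 32623 Ensembl rat genes with a raw count and an FPKM value per library, per the file headers. The deposited FPKM values matched counts divided by the table's exonic length and by the library's summed counts to within 0.00500, the rounding of the file. Summed counts per library ran from 12843875 to 16268464. Rows without a symbol numbered 388 and held 0.0236% of counts; they stayed in the tests under their Ensembl identifiers. Symbols in the gene lists that the table lacked were matched through a RefSeq table of the GRCr8 assembly, used for names only; 575 of 599 symbols named one by one were matched.

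The table held counts, so edgeR 4.0.16 in R 4.3.3 was the main test, as the design written before the data were examined had foreseen. Genes were filtered with filterByExpr (minimum count 10, minimum total count 15), scaled with TMM factors and tested with the quasi-likelihood F-test between groups, with no covariates. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. The biological coefficient of variation was 0.238. Study genes were also fitted without the filter, since Fgf21 failed it, and tested with a two-sided exact permutation test of FPKM over 20 arrangements, which cannot give a p below 0.1. Log2 fold changes are LINC00894 minus vector. Confidence levels are 95%, and count intervals are exact Poisson intervals that cover counting error only.

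A set of 46 gene lists was fixed before the data were examined, of which 44 had at least 3 tested genes. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists. Of the 44 lists, 21 passed at the preset correlation (14 higher, 7 lower) and 0 with an estimated correlation. Genes named in the text followed a rule fixed before the data were examined: the 4 study genes; up to 12 passing genes in each direction, or where fewer than 5 passed, the 8 with the smallest unadjusted p in that direction, with at least 1 FPKM in the higher group, replicates that did not overlap and an approved-style symbol; and up to 4 passing members of each list, or at most 2 with the smallest unadjusted p. Other names are marked in the text as chosen after their values were seen. Not every gene that the rule selects is reported here.

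The edgeR, DESeq2 and camera steps were tested on 5 simulated data sets of 15121 genes with the libraries' means and sizes and 200 changed genes each. The changed genes were drawn only from genes with higher counts, and no library was made to stand apart. edgeR recovered 47.6% of genes changed 2-fold and 97% of those changed 4-fold, with 7.14% of its calls false, above the nominal 5%. DESeq2 recovered 67.8% and 98.2%, with 17.4% of its calls false. camera at the preset correlation called 5 of 5 shifted lists and 0 unshifted lists, by its p before adjustment. Each shifted list held 20 genes with higher counts, all lowered 2-fold, so these calls do not cover smaller shifts or adjusted p-values. Genes were simulated independently of each other, so this does not measure false list calls that come from correlation between genes.

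Alternatives planned before the data were examined were DESeq2 1.42.0, other filters on low values, median-of-ratios scaling, limma on log2 FPKM (pseudocount 1 or 0.1, mean FPKM of at least 0.5) with other scalings and variance models, and each library left out in turn. The limma settings change the tool, the input values, the filter (15892 genes tested against 15121) and the scaling together, and some add a further choice. A difference from edgeR there cannot be put down to any of these alone. Chosen after seeing the data were libraries with Y chromosome counts above 1000 only, presence of such counts as a covariate, removal of each library's length trend, limma-voom with sample quality weights, and KEGG pathways from the table's annotation. Exploratory fits, including the splits of the libraries, were examined before the tests of the closing section were written down. Plots were drawn with matplotlib 3.10.9.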

Results

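The transcriptome of rat brain was measured by poly(A) RNA sequencing in 6 libraries. In 3 libraries the label named the empty expression plasmid pcDNA3.1 (vector), and in the other 3 it named the same plasmid carrying LINC00894, a human long intergenic non-coding RNA (LINC00894). The summed gene counts were 13384733, 16268464 and 15736978 in vector replicates 1, 2 and 3, and 13082945, 12843875 and 13328801 in the LINC00894 replicates. The series title concerns cerebral ischemia and reperfusion, but the sample labels did not state whether these brains were ischemic, nor the region, sex or age of the animals. The labels also did not state that the libraries came from separate animals, so p-values measure the spread between these libraries, which may be technical at least in part. LINC00894 replicates 1 and 2 had 0 counts of the Y-linked Kdm5d and Eif2s3y, while LINC00894 replicate 3 had 491 and 1394. These counts argue against a single animal as the source of the LINC00894 libraries. Whether the vector libraries came from separate animals stays open. No row of the table carried the symbol LINC00894, and its level was not analysed here.

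The first question was whether the genes named in the series title, Eif5, Atf4, Fgf21 and Acod1, differed between LINC00894 and vector brains. Acod1, which encodes the mitochondrial enzyme that makes itaconate in activated myeloid cells, was nearly undetected in vector libraries and low but present in all LINC00894 libraries. Its counts were 2, 4 and 0 in vector replicates 1, 2 and 3 and 24, 27 and 31 in the LINC00894 replicates. Its level was 0.0367 ± 0.0351 FPKM in vector and 0.593 ± 0.0702 FPKM in LINC00894 (mean ± SD, n = 3 each). The summed counts, 6 against 82, gave a depth-scaled ratio of 15.8 with a 95% exact Poisson interval of 6.96 to 44.3, which covers counting error only. Eif5, a translation initiation factor that acts in start codon selection, stood at 112 ± 10.7 FPKM in vector and 133 ± 6.08 FPKM in LINC00894, and the replicates of the groups did not overlap. Atf4, the transcription factor of the integrated stress response, stood at 126 ± 15.2 FPKM in vector and 146 ± 38.7 FPKM in LINC00894, with overlapping replicates. Fgf21, a secreted stress hormone, had 4, 16 and 4 counts in vector and 19, 4 and 6 counts in LINC00894.

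For Acod1 the log2 fold change of LINC00894 over vector was 3.83 (SE 0.66, 95% interval 2.34 to 5.32) by edgeR's quasi-likelihood test. Its Benjamini-Hochberg adjusted p from edgeR was 0.981 over all genes tested and 0.000876 adjusted over the list alone, the 4 study genes. DESeq2 gave Acod1 a Benjamini-Hochberg adjusted p of 0.0144. The 4 genes come from the series title, which may rest on these samples, so the value over the list alone is not independent evidence of a direction. The log2 fold changes of Eif5, Atf4 and Fgf21 were 0.18 (SE 0.14), 0.14 (SE 0.20) and 0.43 (SE 0.73), each within 2 standard errors of 0. Two-sided exact permutation tests of the FPKM values gave p = 0.1 for Acod1 and Eif5, the smallest value that 3 against 3 libraries allow, and p = 0.5 for Atf4 and Fgf21. Without LINC00894 replicate 3 the log2 fold change of Atf4 was -0.04, and without LINC00894 replicate 1 that of Fgf21 was -0.49. Per the table's coordinates, whose genome build is not given in the sources used here, Acod1 (ENSRNOG00000009919) lies on chromosome 15 from 93612971 to 93622358, and Eif5 (ENSRNOG00000010218) on chromosome 6 from 136004214 to 136011406. Atf4 (ENSRNOG00000017801) lies on chromosome 7 from 121480723 to 121482772, and Fgf21 (ENSRNOG00000020990) on chromosome 1 from 101595579 to 101596822.

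**Figure D1:**
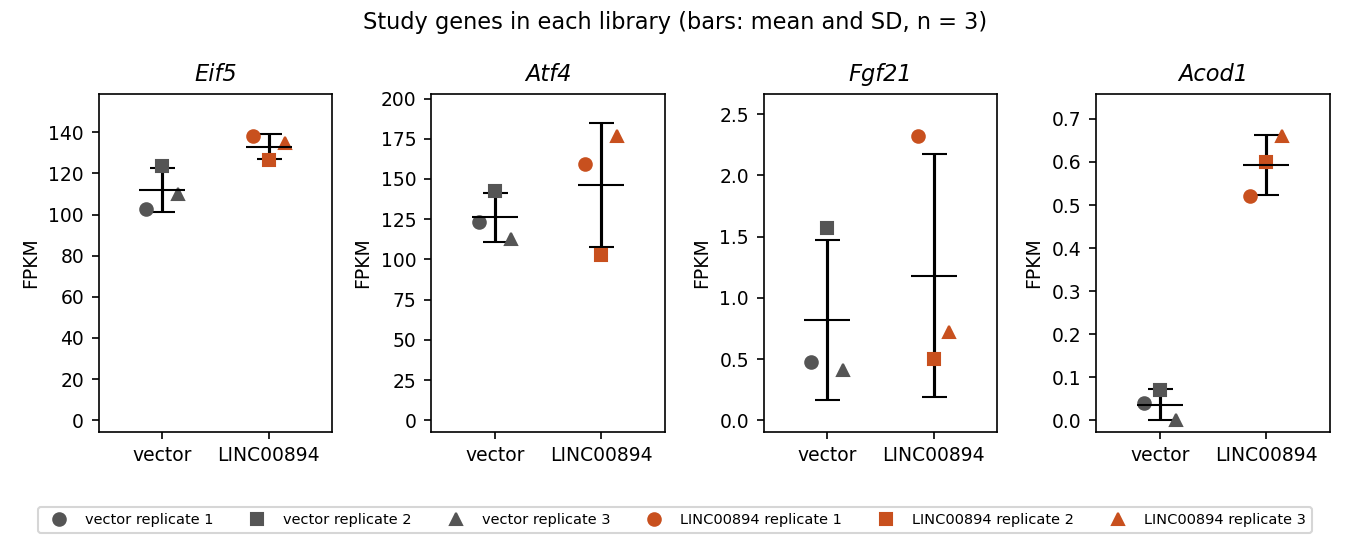
FPKM (vertical axis) of Eif5, Atf4, Fgf21 and Acod1 in each of the 3 vector and 3 LINC00894 libraries, with the mean and SD of each group as black bars. Acod1 lies at 0.07 FPKM or below in the vector libraries and at 0.52 FPKM or above in the LINC00894 libraries, while the groups overlap for Atf4 and Fgf21.

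The second question was which other genes differed. Among 15121 genes tested, 0 passed a Benjamini-Hochberg adjusted p of 0.05 by edgeR, with 610 at an unadjusted p under 0.05 (275 higher and 335 lower in LINC00894) where chance alone would give 756. At that unadjusted p there were 394 genes without LINC00894 replicate 3 and 1104 without LINC00894 replicate 2, and, in fits chosen after seeing the data, 1461 among the 4 libraries with Y-linked counts and 1368 with these counts as a covariate. DESeq2 called 11 genes. It called 9 lower (Egr4, Fosb, Arc, Cacna1g, Creg2, Ddit4, RGD1564664, Fosl2 and Arl4d) and 2 higher (Acod1 and LOC680227); Fosl2, RGD1564664, LOC680227 and Arl4d are named here after their values were seen. In simulated data of this depth and spread, 17.4% of the calls DESeq2 made were false, against 7.14% for edgeR, which recovered 47.6% of genes changed 2-fold and 97% of those changed 4-fold. The simulated changed genes had higher counts and no library stood apart. The recovered shares thus do not cover low genes such as Acod1, nor genes whose level differs strongly in single libraries. The 3 libraries of one group lay above the 3 of the other for 1339 genes, 8.86% of those tested, where chance gives 10%. edgeR called 8 genes without a filter on low counts, 2 without vector replicate 1 (Egr4 and Fosb) and 9 without LINC00894 replicate 3. The 8 were 4 lower (Egr4, Fosb, Arc and Nr4a1) and 4 higher: Acod1 and the X-linked LOC680227, AABR07039356.2 and ENSRNOG00000055225. These 3 X-linked rows were also among the 9, where the remaining LINC00894 libraries had 0 counts of the Y-linked Kdm5d and Eif2s3y. Nr4a1, AABR07039356.2 and ENSRNOG00000055225 are also named here after their values were seen. On log2 FPKM with a pseudocount of 1, scaled by each library's summed counts but without TMM factors, limma called 0 genes. Of its 714 genes at an unadjusted p under 0.05, 510 were higher in LINC00894, against 275 of 610 by edgeR.

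None of the genes in this paragraph passed edgeR's adjusted p over all genes; they had the smallest unadjusted p in each direction among genes with replicates that did not overlap. Egr4, a zinc finger transcription factor induced by neuronal activity, was lower in LINC00894, at 30.8 ± 18.3 FPKM in vector and 4.21 ± 0.983 FPKM in LINC00894 (log2 fold change -2.94, SE 0.45). Fosb stood at 43.4 ± 31.2 FPKM in vector and 8.25 ± 0.878 FPKM in LINC00894 (-2.46, SE 0.47). Arc, a regulator of synaptic strength, stood at 43.3 ± 20.1 and 15.8 ± 2.85 FPKM (-1.53, SE 0.31), and Homer1, a postsynaptic scaffold, at 45.1 ± 7.75 and 28.1 ± 2.37 FPKM (-0.75, SE 0.17). Cacna1g, which encodes a T-type calcium channel, had a log2 fold change of -0.92 (SE 0.18) and Creg2 one of -1.32 (SE 0.30). Ddit4, an inhibitor of mTORC1, and Sgk1, a kinase induced by glucocorticoids, had log2 fold changes of -0.69 and -0.63 (SE 0.14 each). On the higher side, Gsta1, a glutathione transferase, stood at 26.2 ± 0.456 FPKM in vector and 44.1 ± 4.56 FPKM in LINC00894 (0.68, SE 0.15). The endothelial transcription factor Sox18 had a log2 fold change of 1.63 (SE 0.42) and the endothelial heat shock protein gene Hspa12b one of 0.79 (SE 0.22). Lilrb4, an inhibitory receptor of myeloid cells, and Aif1, the microglial marker Iba1, had log2 fold changes of 1.52 (SE 0.41) and 0.85 (SE 0.24). Lgals9, Serpinb9 and Lsm10 had log2 fold changes of 0.88 (SE 0.22), 0.90 (SE 0.26) and 0.88 (SE 0.26).

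Immediate early genes, which neurons induce within minutes of activity, were lower as a group in LINC00894. Of 22 members tested, 20 were lower, 15 of them at an unadjusted p under 0.05, and the median log2 fold change was -1.12. By edgeR with Benjamini-Hochberg adjustment, 0 members passed over all genes and 13 passed adjusted over the list alone. limma's camera test with a preset correlation gave the list an adjusted p of 4.46e-31, and the call was lost with an estimated correlation (adjusted p = 0.46 with an estimated correlation). Nr4a1 stood at 15.0, 48.0 and 102.7 FPKM in vector replicates 1, 2 and 3 and at 11.2, 12.6 and 12.6 FPKM in the LINC00894 replicates. The list's median deviation from each gene's mean over the libraries was -0.10, 0.71 and 1.19 log2 units in vector and -0.24, -1.04 and -0.45 in LINC00894, so vector replicate 1 lay close to LINC00894 replicate 1. The list's median log2 fold change was -0.67 by limma with sample weights and -0.91 by limma without them. Ier2 and Ccn1 were the members with a positive log2 fold change, 0.25 (SE 0.33) and 0.08 (SE 0.56). Of the members named in this paragraph, Nr4a1, Ier2 and Ccn1 were chosen after their values were seen. The glucocorticoid response list had a median of -0.57, with 10 of 12 members lower and 1 lower adjusted over the list alone (camera adjusted p = 4.34e-06 with the preset correlation, adjusted p = 0.476 with an estimated correlation); its Per1, also a clock gene, had a log2 fold change of -1.13 (SE 0.35).

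**Figure D2:**
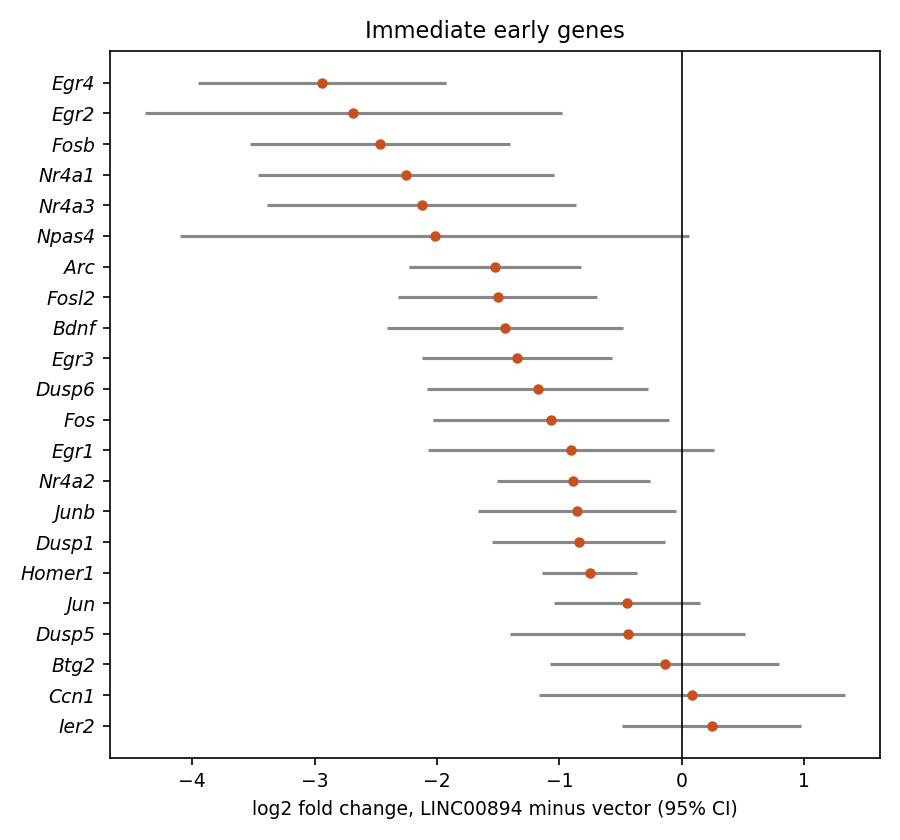
Log2 fold change of LINC00894 over vector (horizontal axis) for the 22 immediate early genes, each point with its 95% confidence interval from edgeR. Egr4 lies lowest at -2.94 and 20 of the 22 points lie below 0.

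Cytosolic ribosomal protein genes had a small positive median in LINC00894, with uneven values between its libraries. Of 81 tested, 80 were higher, the median log2 fold change was 0.36, and 0 passed edgeR's adjusted p over all genes or adjusted over the list alone (7 at an unadjusted p under 0.05). camera gave an adjusted p of 1.82e-23 with the preset correlation, and the call was lost otherwise (adjusted p = 0.546 with an estimated correlation). The median was 0.23 without LINC00894 replicate 3, and by library it was -0.10, -0.04 and -0.37 in vector and 0.32, -0.17 and 0.37 in LINC00894, so LINC00894 replicate 2 lay below vector replicates 1 and 2. Many ribosomal protein genes have near-identical processed copies, so the split of reads between them is uncertain. Rps4y2 and Rps9, with the smallest unadjusted p, stood at 1.22 ± 0.14 and 0.803 ± 0.0404 FPKM in vector and at 3.38 ± 1.75 and 1.74 ± 0.465 FPKM in LINC00894. Proteasome subunits were higher in 36 of 36 genes, with a median of 0.19 (camera adjusted p = 1.39e-06 preset, adjusted p = 0.648 with an estimated correlation); Psma6 and Psmb6 had log2 fold changes of 0.40 (SE 0.17) and 0.36 (SE 0.16). The proteasome median was 0.11 without vector replicate 3 and 0.089 without LINC00894 replicate 3. Translation initiation factors had a median of 0.16 (42 of 52 higher, camera adjusted p = 0.00141 preset, adjusted p = 0.648 with an estimated correlation), a call that ended without vector replicate 3, LINC00894 replicate 1 or LINC00894 replicate 3 (medians 0.07, 0.05 and 0.11, against 0.24 without vector replicate 2). The X-linked Eif2s3, with a log2 fold change of 0.63 (SE 0.20), had the smallest unadjusted p of that list. It stood at 61.5 and 50.4 FPKM in LINC00894 replicates 1 and 2, which had 0 counts of the Y-linked Kdm5d and Eif2s3y, at 36.0 FPKM in LINC00894 replicate 3 and at 28.8 to 31.9 FPKM in vector. Nuclear genes of oxidative phosphorylation had a median of 0.15 (68 of 71 higher, camera adjusted p = 0.000358 preset, adjusted p = 0.756 with an estimated correlation), a call that ended without vector replicate 3 (median 0.08) or LINC00894 replicate 3 (-0.06). Over all 20 alternatives that call held in 17. Across genes, which are not independent replicates, the log2 fold change was lower in longer genes: among 5 bins of exonic length its median was 0.119 in the shortest and -0.0908 in the longest (Spearman's rho -0.259). This trend was uneven between libraries. The slope of log2 CPM per doubling of exonic length was 0.005, 0.017 and 0.062 in vector and -0.0005, 0.016 and -0.100 in LINC00894. It was thus largest in size in vector replicate 3 and LINC00894 replicate 3.

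Targets of Atf4 did not pass the list test as a group. Of 31 tested targets of ATF4 and the integrated stress response, 21 were higher and 10 lower, with a median log2 fold change of 0.07 (camera adjusted p = 0.754 preset, 0.911 estimated). Ddit4 alone passed adjusted over the list alone, and it was lower; Gdf15 stood at 1.71 ± 0.501 FPKM in vector and 4.03 ± 3.1 FPKM in LINC00894. Endoplasmic reticulum chaperones and unfolded protein response genes had a median of 0.04, heat shock proteins 0.12, and apoptosis and p53 targets 0.16, with camera adjusted p of 0.423, 0.366 and 0.618 at the preset correlation. The itaconate and FGF21 pathway list had a median of 0.01, with Acod1 the member that passed adjusted over the list alone. NRF2 antioxidant targets had a median of 0.34 (11 of 14 higher, camera adjusted p = 0.00878 preset, adjusted p = 0.648 with an estimated correlation), with Nqo1 at 0.72 (SE 0.29) and Osgin1 at 1.24 (SE 0.51). That call ended without vector replicate 3 or LINC00894 replicate 1 (medians 0.14 and 0.07), and the median was 0.52 without LINC00894 replicate 2 and 0.21 without LINC00894 replicate 3. Cholesterol synthesis genes were lower in 16 of 16, with a median of -0.23 (camera adjusted p = 1.14e-06 preset, adjusted p = 0.546 with an estimated correlation), and the median was -0.36 without LINC00894 replicate 3. In fits chosen after seeing the data, the cholesterol call ended among the 4 libraries with Y-linked counts (median -0.12, camera adjusted p = 0.302 preset) and with these counts as a covariate (median -0.12, 0.267 preset). Hypoxia and glycolysis targets had a median of -0.22 (15 of 17 lower, camera adjusted p = 0.0119 preset, adjusted p = 0.648 with an estimated correlation), a call that ended without vector replicate 1, vector replicate 2 or LINC00894 replicate 2 (medians -0.11, -0.11 and -0.16).

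Immune and endothelial lists were higher on average in LINC00894, but unevenly between its libraries. Interferon-stimulated genes had a median of 0.44 with 21 of 23 higher (camera adjusted p = 5.43e-06 preset, adjusted p = 0.546 with an estimated correlation), with Ifi44 at 2.83 ± 0.178 FPKM in vector and 4.23 ± 0.16 FPKM in LINC00894. That median was 0.20 without LINC00894 replicate 1, and by library the list lay at -0.24, -0.27 and -0.05 in vector and at 0.58, -0.20 and 0.14 in LINC00894. Endothelial genes had a median of 0.56 with 12 of 12 higher (camera adjusted p = 0.000199 preset, adjusted p = 0.546 with an estimated correlation), and macrophage genes one of 0.58 with 11 of 15 higher (0.00147 preset, adjusted p = 0.581 with an estimated correlation); both calls ended without LINC00894 replicate 1 (medians 0.22 and 0.14), and the medians were 0.36 and 0.25 without vector replicate 3. Microglial genes had a median of 0.28 (13 of 17 higher, camera adjusted p = 0.00583 preset, adjusted p = 0.546 with an estimated correlation), a call that ended without LINC00894 replicate 2 or LINC00894 replicate 3 (medians 0.30 and 0.17); the median was 0.12 without vector replicate 2, 0.16 without vector replicate 3 and 0.44 without LINC00894 replicate 1. Inflammatory cytokines and chemokines had a median of 0.42 (18 of 22 higher, camera adjusted p = 0.00599 preset, adjusted p = 0.67 with an estimated correlation), and neutrophil genes one of 0.55 (6 of 6 higher, 0.0308 preset, adjusted p = 0.581 with an estimated correlation). Both calls ended without vector replicate 3, LINC00894 replicate 1 or LINC00894 replicate 3, where the inflammatory medians were 0.16, -0.08 and 0.36 and the neutrophil medians 0.63, 0.07 and 0.67. They also ended by limma on log2 FPKM with a pseudocount of 1 or 0.1. Over all 20 alternatives the inflammatory call held in 10 and the neutrophil call in 9. The inflammatory and neutrophil medians were 0.65 and 0.83 without vector replicate 1 and 0.76 and 0.94 without LINC00894 replicate 2. Reactive astrocyte genes had a median of 0.38 (12 of 16 higher, camera adjusted p = 0.0131 preset, adjusted p = 0.745 with an estimated correlation), which was 0.74 without vector replicate 2, 0.06 without vector replicate 3 and -0.29 without LINC00894 replicate 1. The reactive astrocyte call ended without vector replicate 3 or LINC00894 replicate 1, and it held in 9 of 20 alternatives. By library, the inflammatory list stood at 0.29, 0.18 and -0.79 log2 units from the mean in vector replicates 1, 2 and 3, and at 1.01, -0.64 and 0.43 in the LINC00894 replicates. In the inflammatory, macrophage, neutrophil and reactive astrocyte lists, vector replicate 3 and LINC00894 replicate 2 had the lowest medians and LINC00894 replicate 1 the highest.

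Glutamatergic and pan-neuronal markers had negative medians in LINC00894, with the lowest values in its replicate 1. By library the pan-neuronal list lay at 0.16, 0.05 and 0.02 in vector and at -0.42, 0.11 and 0.06 in LINC00894, and the glutamatergic list at 0.28, 0.09 and 0.10 in vector and at -0.48, 0.16 and -0.28 in LINC00894. Among both lists and the GABAergic and striatal markers 0 passed edgeR's adjusted p, and DESeq2's 11 genes included none. At an unadjusted p under 0.05, 1 glutamatergic marker was lower, while Pvalb of the GABAergic list (log2 fold change 0.64, SE 0.24) and Gpr6 of the striatal list (0.51, SE 0.21) were higher. Glutamatergic neuron markers had a median log2 fold change of -0.34 with 11 of 13 lower (camera adjusted p = 0.000137 preset, adjusted p = 0.546 with an estimated correlation), a call that ended without LINC00894 replicate 1 (median -0.15, against -0.56 without LINC00894 replicate 2); Tbr1 stood at 36.6 ± 10.9 FPKM in vector and 26.6 ± 4.21 FPKM in LINC00894. Pan-neuronal and synaptic genes had a median of -0.17 with 16 of 18 lower (camera adjusted p = 0.00878 preset, adjusted p = 0.648 with an estimated correlation), a call that ended without vector replicate 1 or LINC00894 replicate 1 (medians -0.11 and -0.04, against -0.28 without LINC00894 replicate 2). Among region markers, the striatal list had a median of 0.17 (camera adjusted p = 0.0191 preset, adjusted p = 0.648 with an estimated correlation) and the hypothalamic list one of -0.66 over 6 genes (0.0321 preset, adjusted p = 0.546 with an estimated correlation). The striatal call ended without vector replicate 1, vector replicate 2, LINC00894 replicate 1 or LINC00894 replicate 3 (medians 0.10, 0.06, 0.15 and 0.10), and its median was 0.35 without vector replicate 3. The hypothalamic call ended without vector replicate 2, vector replicate 3, LINC00894 replicate 2 or LINC00894 replicate 3 (medians -0.25, 0.02, -0.55 and -0.44). The hypothalamic median was also closer to 0 without a low-count filter (-0.17), with a mean FPKM of at least 2 (-0.16) and by limma on log2 FPKM (-0.05 to -0.23 under its 6 settings). Astrocyte, oligodendrocyte and GABAergic neuron lists had medians of -0.05, -0.13 and -0.12, with camera adjusted p of 0.366, 0.366 and 0.618 at the preset correlation.

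**Figure D3:**
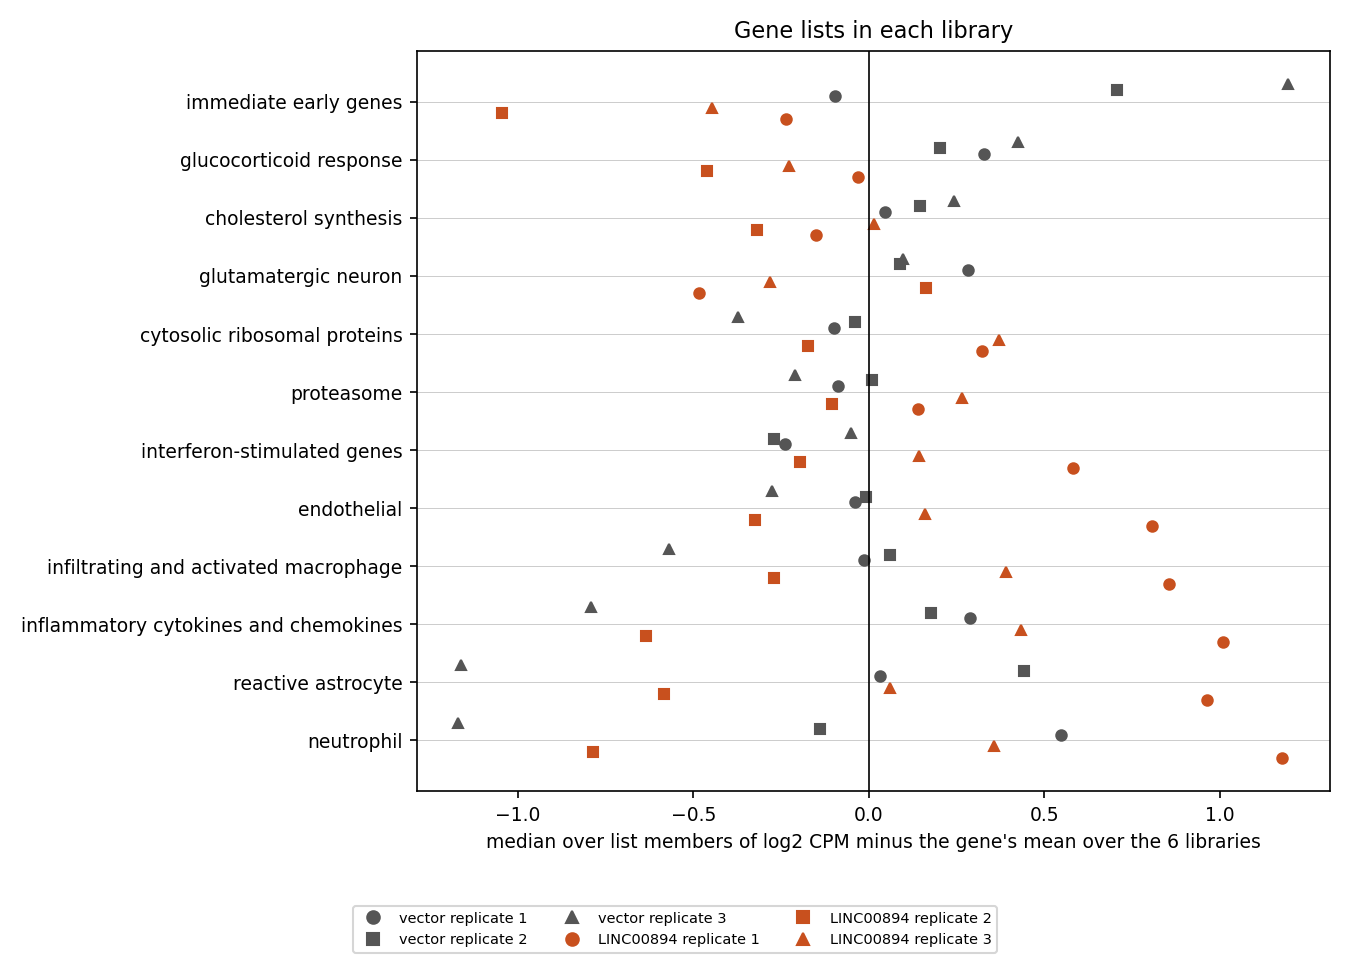
Median over the members of each list of log2 CPM minus the gene's mean over the 6 libraries (horizontal axis), 1 point per library, for 12 lists. The immediate early genes lie at -0.10, 0.71 and 1.19 in vector and at -0.24, -1.04 and -0.45 in LINC00894, and LINC00894 replicate 1 lies above the other libraries for the inflammatory list at 1.01.

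The libraries also differed in sex-linked transcripts. The Y-linked genes Kdm5d, Eif2s3y and Ddx3 had between 501 and 3065 counts per gene in the vector libraries and 491, 1394 and 2081 counts in LINC00894 replicate 3, and 0 counts in LINC00894 replicates 1 and 2. The X-linked LOC680227 had 1550 and 2083 counts in LINC00894 replicates 1 and 2 and 15 or fewer in the other 4 libraries. Ddx3 and LOC680227 were chosen after their values were seen. The groups were thus unbalanced for sex-linked expression, with 4 libraries carrying counts of these Y-linked genes and 1 of them in the LINC00894 group. Among those 4 libraries, compared after seeing the data, the log2 fold change of Acod1 was 3.98 and the median of the immediate early genes -1.17, while that of Fgf21 was -0.27. This comparison, like the fit with Y-linked counts as a covariate, sets the vector libraries against LINC00894 replicate 3 alone, so a call that ended there does not tie a list to sex-linked expression. Calls ended with medians closer to 0 for the cholesterol (-0.12), endothelial (0.28), reactive astrocyte (0.04), pan-neuronal (-0.07) and hypothalamic (-0.24) lists. Calls also ended for the macrophage (0.54), neutrophil (0.50), NRF2 (0.30), hypoxia (-0.19) and striatal (0.33) lists. Medians over 1.5 times as large as among all libraries were those of the nuclear oxidative phosphorylation (0.48), proteasome (0.35), microglial (0.52) and striatal lists and of the list of study genes (0.41). With the covariate the same calls ended, as did those of the glucocorticoid (median -0.57, camera adjusted p = 0.0744 preset) and glutamatergic lists (-0.50, 0.0522 preset). Pearson correlations of log2 CPM, scaled with TMM factors, averaged 0.969 within groups and 0.969 between groups. The first principal component of the same values, with 35.5% of the variance, placed vector replicate 3 at 53.2 and the other libraries between -27.2 and 15.8. No pair of libraries lay within sampling noise of each other (chi-square per degree of freedom of 14.1 or more).

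**Figure D4:**
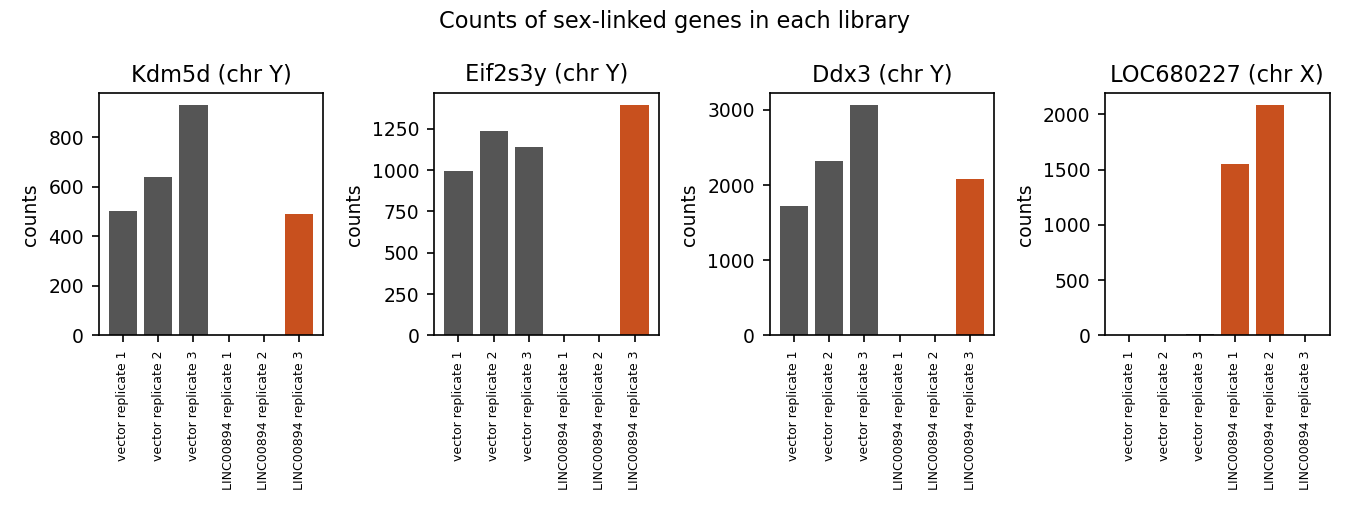
Counts (vertical axis, from 0) of the Y-linked genes Kdm5d, Eif2s3y and Ddx3 and of the X-linked LOC680227 in each of the 6 libraries, 1 bar per library. LINC00894 replicates 1 and 2 have 0 counts of the 3 Y-linked genes and 1550 and 2083 counts of LOC680227.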

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

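Tests on libraries with Y-linked counts, with Y-linked counts as a covariate, with the length trend removed, by limma-voom and on KEGG pathways were chosen after seeing the data. edgeR called 0 genes; DESeq2 called 11 and edgeR without a low-count filter 8, while 0 were called by limma on log2 FPKM under its 6 settings, by limma-voom, with a mean FPKM of at least 2, with median-of-ratios scaling, in libraries with Y-linked counts, with the Y-linked covariate or without the length trend. Leaving out each library in turn gave 0 to 9 genes. Without LINC00894 replicate 3 the 9 were 5 on chromosome Y, 3 on X, and Egr3; the remaining LINC00894 libraries had 0 counts of Kdm5d, Eif2s3y and Ddx3 (Egr3 and Ddx3 are named after their values were seen). Genes at an unadjusted p under 0.05 numbered 610, ranged from 394 to 1104 over the left-out libraries, and were 1461 in libraries with Y-linked counts, 1368 with the covariate and 975 without a low-count filter.

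Acod1 stayed higher in each of its 20 alternatives, at 0.53 to 4.66, and at 3.24 to 4.66 over the left-out libraries; limma on log2 FPKM, where the pseudocount understates low genes, gave 0.53 to 2.37. It passed without a low-count filter (3.82, edgeR adjusted p = 0.0402) and by DESeq2 (3.90, adjusted p = 0.0144), in a range of adjusted p from 0.0144 to 0.9998 over all alternatives. Leaving out 1 library put Eif5 at 0.12 to 0.24, Atf4 at -0.036 to 0.31 and Fgf21 at -0.49 to 1.31. Fgf21 was also reversed in libraries with Y-linked counts (-0.275) and with the Y-linked covariate (-0.270); the cause was not tested.

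Lists past the preset-correlation test numbered 21, 14 to 23 with 1 library left out, and 11 with the Y-linked covariate. Of the 21, 4 held under all their alternatives (immediate early genes, ribosomal proteins, proteasome and interferon-stimulated genes) and 7 without each library in turn. Both the 21 and the 7 include the list of study genes. It comes from the series title, which may rest on these samples, so its call is not independent evidence. With an estimated correlation 0 lists passed in any setting where it was run; it was not run for DESeq2. The direction of camera for the reactive astrocyte list turned by limma with sample weights, where its median stayed positive (0.0311), and the list had medians from -0.29 to 0.74 with 1 library left out; nuclear oxidative phosphorylation ran from -0.062 to 0.23 and was 0.48 with the Y-linked covariate. The cause was not tested. Of 338 KEGG pathways, 100 passed at the preset correlation and 0 with an estimated one. The protein-coding alternative was not run, because the table gives no biotype. No paired analysis was possible because the replicate numbers pair nothing. Fgf21 had 4 to 19 counts per library and failed the low-count filter.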

Other observations

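All tests in this part were chosen after the results they measure, or values close to them, had been seen, including the splits of the libraries. The mitochondrially encoded genes had a median log2 fold change of -0.14 (camera adjusted p = 0.0554 preset, 0.648 estimated), and mitochondrial genes held 8.92% to 11.1% of counts per library. Hemoglobin and other erythroid genes varied between libraries within groups, with list medians of 1.03, -1.88 and 0.50 log2 units from the mean in vector and 0.60, 0.73 and -0.77 in LINC00894, and a median log2 fold change of -0.03. Lists for choroid plexus, ependymal cells, pericytes and smooth muscle, and fibroblasts and meninges had medians of -0.14, -0.22, -0.23 and -0.13, with camera adjusted p of 0.22, 0.332, 0.22 and 0.436 at the preset correlation. Antigen presentation genes had a median of 0.35, circadian clock genes -0.13, proliferation genes 0.06, oligodendrocyte precursors -0.02 and ubiquitination genes 0.03 (0.101, 0.11, 0.786, 0.618 and 0.841). Lists for cerebellum, thalamus and habenula, hippocampus, and muscle and scalp had medians of -0.03, -0.17, -0.13 and 0.18 (0.101, 0.251, 0.786 and 0.504). Lymphocyte and sex-linked lists had 2 tested members each and were not tested as lists.

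There are 10 ways to split the 6 libraries into 3 and 3, too few for a share under 0.05. By edgeR with Benjamini-Hochberg adjustment, the real split called 0 genes and the highest other 0, so all 10 gave as many; DESeq2 was run on the real split only and called 11. At an unadjusted p under 0.05 the real split gave 610 genes and the highest other 1344, and 6 of the 10 splits gave as many as the real one. That highest split set vector replicates 1 and 3 and LINC00894 replicate 2 against the rest. For lists past the preset-correlation test the real split gave 21, the highest other 25 and the lowest other 11, with 2 of the 10 as high. That test thus called lists in each split that does not follow the groups. The immediate early gene median had a size of 1.12 in the real split and 1.11 in the highest other, with 1 of the 10 as large, and the ribosomal protein median 0.362 and 0.433, with 3 of the 10 as large. Ranked by limma's camera p at the preset correlation, before adjustment, another split gave a smaller value for both lists. For the immediate early genes it was 1.70e-40 with vector replicate 1 and LINC00894 replicates 1 and 2 against the rest, and 1.01e-32 in the real split. For the ribosomal proteins it was 5.07e-31 in the split with the highest median and 8.28e-25 in the real one.

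The first pattern is the lower level of immediate early genes in LINC00894. A single unusual library, vector replicate 3, is argued against as the whole cause, since without it the median was -0.80 with 18 of 22 members lower; limma with sample weights, which give less weight to more variable libraries, put it at -0.67. Fewer glutamatergic neurons are argued against as the whole cause too, since the lower quartile of their markers was -0.51, above the upper quartile of -0.77 of the immediate early genes. Sex of the animals cannot be told apart from the group, because 1 LINC00894 library had Y-linked counts; among libraries with these counts the median was -1.17. Neuronal activity or handling before tissue collection, which the labels do not give, and an effect of LINC00894 itself stay open and may each apply. A difference between libraries that does not follow the groups stays open too: vector replicate 1 lay at -0.10, near LINC00894 replicate 1 at -0.24. With vector replicate 1 grouped with LINC00894 replicates 2 and 3, the median had a size of 1.11, against 1.12 in the real split.

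The second pattern is the presence of Acod1 counts in LINC00894 libraries, for which counting error alone is argued against, since the exact Poisson interval of the count ratio started at 6.96. A larger share of neutrophils, macrophages and microglia with an unchanged profile stays open: of 38 tested markers 0 were higher by the 2.34 log2 units at which the Acod1 interval starts (highest Msr1, 1.35, named after its values were seen), but none had a vector level as low as that of Acod1, so a small influx could be hidden. LINC00894 replicate 2, with 27 Acod1 counts, had neutrophil and macrophage medians of -0.79 and -0.27, below those of vector replicates 1 and 2, and a microglial median of 0.14, above each vector library, and 1 library alone excludes nothing. Sex of the animals cannot be told apart from the group for the reason given above, with a log2 fold change of 3.98 among libraries with Y-linked counts. An effect of LINC00894 on Acod1 may apply and was not tested apart from these.

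The third pattern is the higher level of ribosomal protein genes. The length trend is argued against as the whole cause, since with each library's trend removed the median was 0.273, against 0.362 before. Random lists matched on exonic length had a median of 0.108 (SD 0.0344 over 10000 lists), so part of the shift may come from length. A single library is argued against as well, since the lowest median with 1 library left out was 0.227. What stays open is a difference between libraries that does not follow the groups: LINC00894 replicate 2 lay at -0.17, below vector replicates 1 and 2.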
